A study of Mus musculus with 15 samples.

How the data were processed

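Total RNA from EpiSC cultures was extracted with TRI-Reagent (Sigma), treated with DNase I, and 200 ng of it labelled for 2-colour hybridisation on Agilent SurePrint mouse mRNA arrays, per the labels' protocols. The 15 samples fell into 5 groups of 3 by arm and day: day 5, DA day 9, DA day 14, control day 9 and control day 14. Each sample was 1 channel, Cy3 or Cy5, of 8 arrays on 2 slides. The Cy5 channel of 1 array holds no sample that the labels name, and its columns were not used here. Feature Extraction 11.5.1.1 wrote the scanner intensities of each spot (median signal, local background and processed signal), per the file headers, which also give mm9 as the build of the array design. The deposited table of values over the whole series was on a log2 scale, with column medians between 6.33 and 6.35. Over 15255 probes with a mean log2 intensity above 8, its columns had slopes of 1.01 to 1.03 on the normalised log2 intensities of their own channels. With each probe centred on its mean over samples, each of the 15 columns correlated best with its own channel (r 0.821 to 0.993). Some margins were small, such as that of control day 9 replicate 3 (0.821, against 0.814 for another channel). What the authors did to make those log2 values stays unknown beyond limma 3.20.9 being named in the submitters' processing notes, and it was used only as an alternative. They cover 45291 of 55821 probes.

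Scanner intensities were background corrected per channel by normexp with an offset of 50 on all spots (limma 3.58.1 in R 4.3.3, and version 1.17.8 of data.table) and put on the log2 scale. Control spots were then left out, as were the 147 to 229 spots per channel that Feature Extraction marked as outliers, and 0 spots were saturated. Per channel, 54.7% to 65.6% of probes lay well above background, by the Feature Extraction flag. Spots of a probe were averaged, and the 15 channels were quantile normalised. A probe was tested when it lay well above background in at least 3 of the 15 channels and had a value in at least 10. Of 55681 probes, 27656 were named by matching their RefSeq accession, without its version, to the RefSeq gene table of GRCm38.p6, from which only names were taken. The other 28025 stayed unnamed here. The named probes covered 20972 genes, of which 15859 were tested, each by its brightest probe. For 4209 genes more than 1 probe passed the filter, and between 39 and 400 of them in a comparison had another probe called in the opposite direction.

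Groups were compared in 1 limma fit over all 15 samples with terms for group and dye and with array as a random block (consensus correlation 0.504), followed by eBayes. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison are called higher or lower, rising or falling. The fit had 9 residual degrees of freedom, 13.1 with those eBayes adds. Fold changes are those of the fit, which weighs samples by the array they share and adjusts for dye, so they differ from differences of the printed group means, which are ± SD. For Ddc at day 14 the fit gave 4.71, and 5.03 without the array block. The median SE of a log2 fold change was 0.0772 to 0.12 over the 7 comparisons. The offset pulls fold changes of dim genes toward 0. A gene none of whose probes lay well above background in any sample of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group over the mean, in the other, of the higher of its own signal and the lowest signal well above background on that channel. Being made from group means, it can exceed the fitted fold, which is no bound. No fold is given where neither group had the gene well above background.

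Gene lists were tested with limma's cameraPR on the moderated statistics with a preset correlation of 0.01 between genes, adjusted over the 33 lists within a comparison, and again with each list's correlation estimated from the residuals. The list test compares a list with all other genes. Counts of members are given over all genes tested and adjusted over the list alone. A list's median with genes at their bounds differed from the fitted median by at most 0.035 in every list past the threshold of the list test in the 6 comparisons of 2 groups. Named genes are the 10 largest rises and 10 largest falls for the comparisons of DA with control cells, and 5 each way for the others, among genes past the threshold whose samples did not overlap, leaving out names that are clone or locus identifiers. To these were added 15 genes of the dopaminergic and hedgehog programmes and of pluripotency, fixed in advance, and for each list the 4 members past the threshold with the largest change, or the 2 members with the lowest p where fewer than 2 passed. The text names part of the list members, and some results that this rule gives are not reported here. Overlap of samples was not asked for in the interaction. The groups, the model, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the averaging of close replicates and the values on slide 1 alone.

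Replicates were compared with the noise between spots of the same probe within an array, estimated from probes with 10 spots. Both measures used only a mean log2 intensity above 8. The lowest ratio of a difference between samples of a group to that noise was 0.655, and the lowest between groups was 2.26. Samples that close may share a culture or an RNA preparation. They were kept as 3 samples per group, as the labels number them and since they are separate channels with different values, and a fit with them averaged to 1 sample each, without array block, was added and its counts stand beside the others. All pairs closer than that noise lay on slide 2. Pairs of a group on different slides differed most, with a robust SD of 0.2 to 0.268 log2 units. A shared slide can thus not be told apart here from a shared culture or RNA preparation. Slide was tested as a fixed block and by keeping the 11 samples of slide 2. Further alternatives were the Feature Extraction processed signals, scaling to the 75th percentile, loess within and Aquantile between arrays with a separate-channel fit, no filter on dim probes or one of 8 channels, the mean over probes of a gene, no dye term, no array block, the replicate number as a block, only the samples of the groups compared, the deposited log2 values, and each replicate left out in turn.

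The fit and the list test were tested on simulated normalised values built for the comparison of DA with control cells at day 9 over 15837 genes. Background correction, normalisation, the filter and the choice of probe were not run on them, and no slide difference was simulated. Only 200 genes were changed, against 50.3% of genes called in the data, so the rates below may not hold there. With 50 genes changed by each size, 16% of changes of 0.25 log2 units were recovered, 80% of 0.5, and 100% of 1 and of 2, and 7 of 155 calls were false. In an unchanged comparison 0 genes were called. Of 200 unchanged lists, 2 had a p under 0.05. The simulated genes varied independently, so this does not show how the list test behaves where the genes of a list are correlated.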

Results

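Gene expression was measured in mouse epiblast stem cells (EpiSC, cultured pluripotent cells of the epiblast stage) from animals that carry a green fluorescent reporter at Pitx3, a transcription factor gene of midbrain dopaminergic neurons. The cells were differentiated over 14 days. Cells of the dopaminergic arm, called DA cells here, received the morphogens sonic hedgehog (SHH) and FGF8 from day 5, and control cells received neither. RNA was profiled at day 5, before the morphogens were added, and at days 9 and 14 in each arm. Each of these 5 groups held 3 samples, 15 in all, and each sample was 1 colour channel of a 2-colour array. Between 54.7% and 65.6% of probes lay well above background in a sample, and the median spot signal was 41 to 79 intensity units over a median local background of 31 to 43. The number of arrays limits the precision of every value.

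The groups separated by day and by arm. The first principal component over all genes tested held 63.1% of the variance, the second 17.1%, and all 3 samples of each group lay together. Across the tested genes with a value in all 15 samples, Pearson's r was 0.988 to 0.998 between samples of a group and 0.896 to 0.980 between samples of different groups. These values are across genes, which are not independent replicates. Over the 9457 of these genes with a mean log2 intensity above 8, a robust SD of the difference between 2 samples was 0.108 to 0.268 log2 units within groups and 0.362 to 0.944 between groups. Replicates 2 and 3 at day 5, all 3 DA day 9 replicates, DA day 14 replicates 2 and 3, and control day 9 replicates 1 and 2 differed by less than the noise between spots of an array. The adjusted p-values therefore measure the spread between these samples, and the sources used here do not say whether the samples of a group came from separate cultures. With such samples averaged and counted once, 1 DA day 9 sample and 2 day 5, 2 control day 9, 2 DA day 14 and 3 control day 14 samples remained, and those counts stand beside the others in each comparison. Slide 1 held 1 day 5, 1 control day 9 and 2 control day 14 samples and no DA sample, so values with slide as a block and values within slide 2 are also given. All pairs closer than the noise between spots lay on slide 2. After averaging, day 5 and control day 9 each held 1 value per slide, so the spread in that fit includes any slide difference. Within slide 2, 2 day 5, 2 control day 9 and 1 control day 14 samples remained beside all DA samples. A group left with 1 sample, there or by averaging, was assumed to vary like the other groups.

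**Figure D1:**
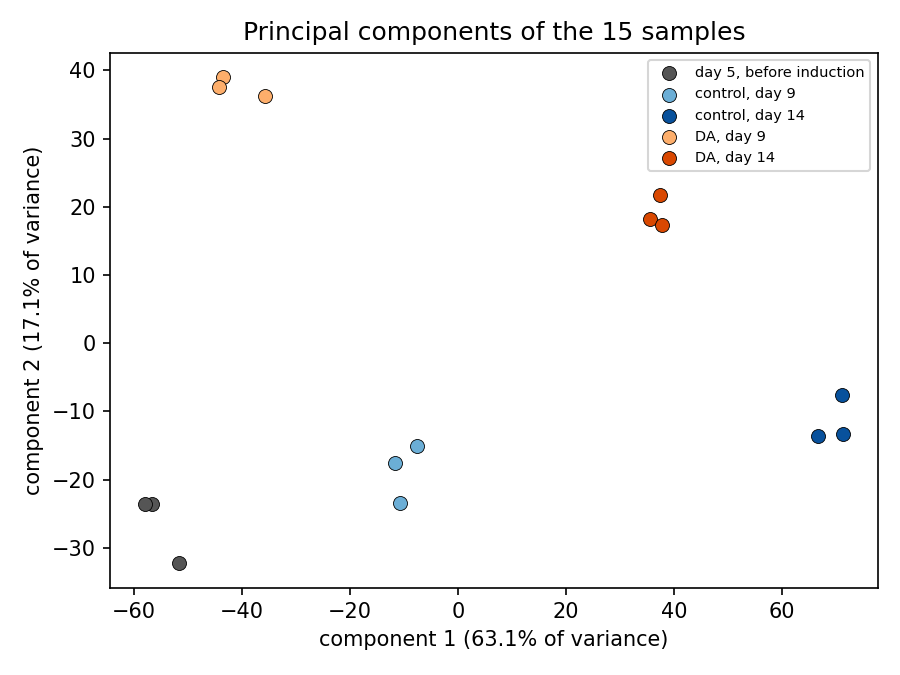
Scores of the 15 samples on principal components 1 and 2 of the normalised log2 intensities, with the percent of variance on each axis, 1 point per sample and 1 colour per group. The first component (63.1%) orders the samples mainly by day, and the second (17.1%) places DA samples above control samples of the same day.

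The comparison of DA with control cells at day 9 asks what the morphogens changed early in the differentiation. Transcripts of the ventral midline and feedback genes of FGF signalling were higher in DA than in control cells, and neuronal transcripts were lower. The floor plate and pan-neuronal list calls, however, were lost with an estimated correlation between genes. Foxa2, a floor plate transcription factor, averaged 12.97 ± 0.26 in DA and 10.41 ± 0.17 in control cells (log2 intensity, SD, n = 3), and Shh, the floor plate's own hedgehog ligand, rose by 2.34 log2 units (SE 0.076, adjusted p = 1.36e-10). Dusp6, a phosphatase that ERK signalling induces, rose by 2.80 log2 units. Dcx and Tubb3, which encode microtubule proteins of young neurons, fell by 2.45 and 2.00 log2 units.

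The largest rises at day 9 were those of Rbp4, a retinol carrier (log2 fold change 3.89, SE 0.135, adjusted p = 2.55e-10), Asb4 (3.77), Cpm, a carboxypeptidase (3.58), and Rgma, a BMP co-receptor and guidance molecule (3.37). Wnt9a (3.26), Bmp7 (3.22), the growth factor receptor gene Egfr (3.16), Mogat2 (3.02), Hlf (3.00) and Hrc (2.98) followed. The largest falls were those of the LIM homeobox genes Lhx2 (-5.80, SE 0.164, adjusted p = 5.56e-11) and Lhx9 (-5.0) and of Dbx1, a homeobox gene of intermediate neural tube progenitors (-5.03). Pdzph1 (-4.03), Prdm12 (-3.85), the microRNA host transcript Mir9-3hg (-3.77), the vesicular glutamate transporter gene Slc17a6 (-3.56), the dorsal neural tube gene Pax3 (-3.53) and Ebf2 (-3.36) also fell. Tfap2b was not well above background in any DA sample and was at least 12-fold lower there. For these 20 genes the direction and the call held with slide as a block and within slide 2, where no value moved by more than 0.127 and 0.32 log2 units.

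At day 9 the genes of the dopaminergic programme did not move as one. Th, which encodes the rate-limiting enzyme of dopamine synthesis, was lower in DA (9.01 ± 0.18) than in control cells (10.18 ± 0.14), a log2 fold change of -1.08 (SE 0.138, adjusted p = 1.81e-05, n = 3). Ddc, the decarboxylase gene shared by dopamine and serotonin synthesis, rose (1.15, adjusted p = 0.00373), and its call was lost within slide 2 (0.98, adjusted p = 0.0527, the highest over its alternatives). Lmx1a, a transcription factor of dopaminergic progenitors, rose by 1.63. Wnt1 (1.40) and the hedgehog receptor gene Ptch1 (1.41, adjusted p = 0.000403) rose as well, and Ptch1 did not pass with the close replicates averaged, which leaves fewer samples (1.26, adjusted p = 0.126, from 2.33e-07 over its alternatives). En1 was at least 1.44-fold higher in DA cells, since no control sample had it well above background. Gli1, a direct hedgehog target, did not pass (0.53, adjusted p = 0.124), except with only the groups compared (0.58, adjusted p = 0.00246, and up to 0.461 over its alternatives), nor did Pitx3 (-0.05), Nr4a2 (-0.23), the monoamine transporter gene Slc18a2 (0.21), or the pluripotency genes Pou5f1 (adjusted p = 0.442) and Nanog (-0.10). Slc18a2 passed without control day 9 replicate 2 (0.37, adjusted p = 0.021) and without DA day 9 replicate 2 (0.40, adjusted p = 0.0282). Nr4a2 passed with slide as a block (-0.29, adjusted p = 0.027) and within slide 2 (-0.32, adjusted p = 0.0189), with adjusted p from 0.0026 to 0.619 over its alternatives. Slc6a3, the dopamine transporter gene, was not well above background in either group.

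Among 14 measured FGF-ERK feedback genes, 11 rose and 0 fell at day 9 (median 0.98, adjusted p = 1.14e-05), with the same counts adjusted over the list alone. Spry1 (2.35), Il17rd (2.19) and Etv4 (1.78) were among them, and the call held with an estimated correlation (adjusted p = 0.0495). The floor plate and midbrain progenitor list had 13 genes higher, 2 lower and 4 not past the threshold (14 and 2 adjusted over the list alone; median 0.82, adjusted p = 0.00258), and Foxa1 (1.81) was among the higher ones, whereas Kcnk10 fell (-2.24). This call was lost with an estimated correlation between genes (adjusted p = 0.115 with an estimated correlation). Hedgehog pathway genes split, with 6 higher and 5 lower of 17 both over all genes and adjusted over the list alone (median 0.10, adjusted p = 0.756). Nkx2-2, a ventral target, rose (2.02), and Gli3 (-3.15) and Gas1 (-1.49), which hedgehog signalling is known to repress, fell. Of the midbrain dopaminergic neuron list 5 genes rose, 5 fell and 12 did not pass, also adjusted over the list alone (median -0.07, adjusted p = 0.805), with Gch1, the first enzyme of tetrahydrobiopterin synthesis, higher (2.72) and Ebf3 lower (-3.36).

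The pan-neuronal and glutamatergic lists were lower in DA than in control cells at day 9. The GABAergic list did not pass (6 genes higher and 6 lower of 17, median -0.07, adjusted p = 0.871). In the pan-neuronal list 25 of 28 measured genes were lower, 1 was higher and 2 did not pass, also adjusted over the list alone (median -1.23, adjusted p = 4.05e-10; adjusted p = 0.0582 with an estimated correlation). The neurofilament genes Nefl (-2.76) and Ina (-2.26) showed the largest changes beside Dcx and Tubb3. Glutamatergic genes fell in 9 of 10 cases, also adjusted over the list alone (median -1.18, adjusted p = 8.86e-05, and 0.000104 with an estimated correlation), among them Nrn1 (-1.67), Eomes (-1.60) and Tbr1, which was at least 3.74-fold lower. Serotonergic genes rose instead, 6 of 7 over all genes and adjusted over the list alone (median 1.23, adjusted p = 0.0103; adjusted p = 0.511 with an estimated correlation), with Fev (1.88), Gata3 (1.35) and Gata2 (1.23). Gata2 and Gata3 also belong to the GABAergic list, Nkx2-2 to the hedgehog list and Ddc to the dopaminergic one, so this list is not specific to serotonergic neurons. With slide as a block, the medians of the FGF-ERK, floor plate, pan-neuronal, glutamatergic and serotonergic lists were 0.93, 0.79, -1.26, -1.18 and 1.23. Within slide 2 they were 1.03, 0.74, -1.21, -1.13 and 1.18.

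Hypoxia and glycolysis genes rose at day 9, 10 of 16 with 1 lower (11 and 1 adjusted over the list alone; median 0.41, 0.42 with slide as a block and 0.47 within slide 2; adjusted p = 0.00398, and 0.0495 with an estimated correlation), led by the hypoxia-induced genes Ndrg1 (2.49) and Adm (1.07). Astrocyte genes had 6 of 11 higher and 0 lower, also adjusted over the list alone (median 0.32, adjusted p = 0.0432), with Aldh1l1 at 1.79 and Aldoc at 1.67. That call was lost with an estimated correlation (adjusted p = 0.0518 with an estimated correlation), with slide as a block (0.27, adjusted p = 0.0506), and without DA day 9 replicate 2 (0.25, adjusted p = 0.0903). It was also lost with the close replicates averaged (0.26, adjusted p = 0.0565) and passed in 14 of 21 alternatives, within slide 2 (0.19) among them. Cell cycle genes had 15 higher and 4 lower of 25, also adjusted over the list alone (median 0.45, adjusted p = 0.0447; adjusted p = 0.751 with an estimated correlation). Plk1 (1.00) and Aurka (0.94), mitotic kinases, rose, and the replication clamp gene Pcna fell (-1.17). The cell cycle call was also lost with slide as a block (0.45, adjusted p = 0.0506) and without control day 9 replicate 2, DA day 9 replicate 2 or DA day 9 replicate 3 (adjusted p = 0.122, 0.0903 and 0.0963), and with the close replicates averaged (0.55, adjusted p = 0.147). It passed in only 9 of 21 alternatives, within slide 2 (0.38) among them.

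Of 15859 genes tested at day 9, 3951 were higher and 4032 lower in DA cells at adjusted p under 0.05 (limma). Scaling to the 75th percentile gave 3525 and 2751 instead. Of the 3951 and 4032 genes, 583 and 577 changed at least 2-fold. Among the 7983 genes past the threshold, 7375 had no overlap between the samples of the groups, and 54.8% of all genes tested had none. Chance gives 10% only where samples are independent, which is not known here. The genes past the threshold were also chosen on these same samples, so neither share excludes chance. The count was 8440 with slide as a block, 8132 within slide 2, and 3536 with the close replicates averaged.

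**Figure D2:**
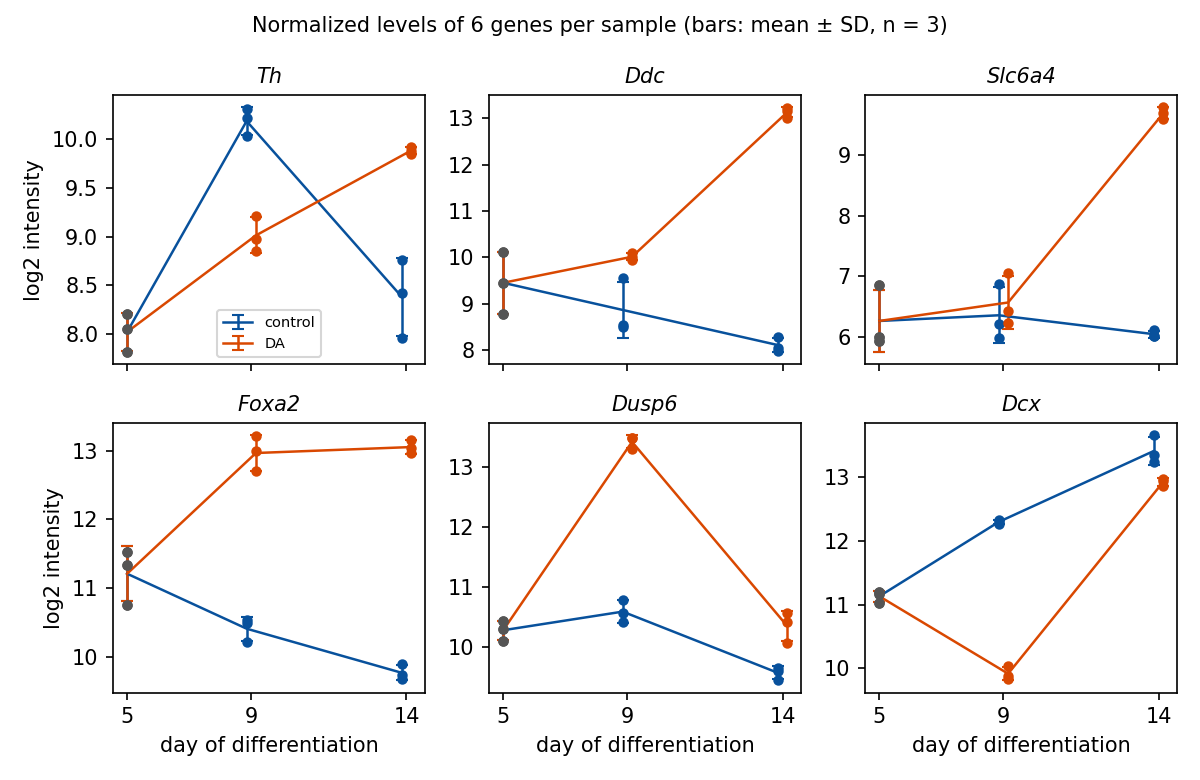
Normalised log2 intensity of Th, Ddc, Slc6a4, Foxa2, Dusp6 and Dcx in each sample by group, with points for samples and bars for the mean ± SD (n = 3). Th was highest in control cells at day 9 (10.18), and Ddc and Slc6a4 were highest in DA cells at day 14 (13.13 and 9.68).

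At day 14 the comparison of DA with control cells asks what the arms had become at the end of the protocol. Ddc averaged 13.13 ± 0.10 in DA and 8.105 ± 0.15 in control cells (log2 intensity, SD, n = 3), a log2 fold change of 4.71 (SE 0.273, adjusted p = 2.25e-08). Th was now higher in DA (9.88 ± 0.033) than in control cells (8.38 ± 0.40), by 1.46 log2 units (adjusted p = 1.39e-06). Slc6a4, the serotonin transporter gene, and Tph2, which encodes the neuronal enzyme of serotonin synthesis, were not well above background in any control sample and were at least 12.4-fold and 9.81-fold higher in DA cells by their group means.

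Other large rises at day 14 were those of Gchfr (4.22) and Gch1 (3.14), a regulator and the first enzyme of tetrahydrobiopterin synthesis, Asb4 (3.83), Foxa2 (3.25), Upp1 (3.00), Mboat1 (3.00) and Ptx3, a secreted pentraxin (2.99). Tfap2b was at least 17.4-fold lower in DA cells, where no sample had it well above background. Lhx9 (-4.05), Lhx2 (-3.15), Spef2, a gene of motile cilia and flagella (-2.78), Rftn2 (-2.76), Gkn1 (-2.74), Plk5 (-2.57), Myo1h (-2.54), the hedgehog co-receptor gene Gas1 (-2.41) and Calca, which encodes calcitonin and a neuropeptide (-2.30), also fell. Another probe of Calca gave the opposite call (0.53, adjusted p = 0.0424). These 20 genes kept direction and call with slide as a block, with moves of at most 0.195 log2 units. Within slide 2, where 1 control day 14 sample remained, the moves were at most 0.35.

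The remaining dopaminergic genes named in advance rose at day 14. Slc18a2 rose by 2.69 (SE 0.121, adjusted p = 3.32e-09), Lmx1a by 2.88, Shh by 2.98, Pitx3 by 1.03, Nr4a2, a transcription factor of dopaminergic neurons, by 0.82, and Slc6a3 by 0.66. En1 was at least 1.39-fold higher. Ptch1 passed (0.91, adjusted p = 0.00846) but not without control day 14 replicate 2 (0.60, adjusted p = 0.173), with no dye term (adjusted p = 0.0842) or in other settings, with adjusted p from 6.8e-06 to 0.36 over its alternatives. Wnt1 passed (0.38, adjusted p = 0.00339) but not within slide 2 (0.22, adjusted p = 0.0737, within a range of 0.00235 to 0.0996 over its alternatives). Gli1 (0.26, adjusted p = 0.444) and Pou5f1 (adjusted p = 0.526) did not pass, and Nanog passed (-0.32, adjusted p = 0.0157) with adjusted p from 0.000701 to 0.353 over its alternatives.

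Floor plate and midbrain progenitor genes rose in 15 of 19 cases with 1 lower at day 14, also adjusted over the list alone (median 1.08, adjusted p = 4.1e-07, and 0.00444 with an estimated correlation), Foxa1 (2.62) among them. In the midbrain dopaminergic neuron list 13 of 22 genes rose, 2 fell and 7 did not pass, also adjusted over the list alone (median 0.45, adjusted p = 0.00183; adjusted p = 0.0718 with an estimated correlation). All 7 measured serotonergic genes rose, also adjusted over the list alone (median 2.36, adjusted p = 2.22e-05, and 0.122 with an estimated correlation). Fev, a transcription factor of serotonergic neurons, rose by 2.36. The other members of that list, Maob, Htr1a, Htr1b and Slc22a3, were not among the genes tested. The filter asks for 3 channels, so a gene can enter a list through the DA day 14 samples alone. The medians of these lists with slide as a block were 1.02, 0.49 and 2.17, and within slide 2 they were 1.21, 0.49 and 1.98.

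Progenitor and dividing-cell genes were higher in DA than in control cells at day 14, and general neuronal genes were lower. Each of these list calls was lost with an estimated correlation (adjusted p = 0.122, 0.186 and 0.245). Cell cycle genes rose in 19 of 25 cases with 0 lower, also adjusted over the list alone (median 0.85, adjusted p = 1.26e-06; adjusted p = 0.186 with an estimated correlation), with the proliferation markers Mki67 (1.28), Nusap1 (1.32) and Ccna2 (1.31). Neural progenitor genes had 13 of 19 higher and 2 lower, also adjusted over the list alone (median 0.48, adjusted p = 0.0169; adjusted p = 0.122 with an estimated correlation), such as Prom1 (2.38) and the intermediate filament genes Vim (1.38) and Nes (1.18). That call was lost without control day 14 replicate 2 (0.41, adjusted p = 0.0609), with the close replicates averaged (0.44, adjusted p = 0.0557) and with only the groups compared (0.43, adjusted p = 0.0539). The pan-neuronal list had 19 of 28 genes lower and 2 higher, also adjusted over the list alone (median -0.54, adjusted p = 0.00011; adjusted p = 0.245 with an estimated correlation), among them Myt1l (-1.07) and Stmn2 (-0.88), whereas Scg2 rose (1.33). Glutamatergic genes had 7 of 10 lower and 1 higher (7 and 2 adjusted over the list alone; median -0.75, adjusted p = 0.00228, and 0.00444 with an estimated correlation), such as Neurod6 (-1.78) and Tbr1 (-1.40). With slide as a block the cell cycle, progenitor, pan-neuronal and glutamatergic medians were 0.87, 0.56, -0.57 and -0.80, and within slide 2 they were 1.03, 0.55, -0.84 and -0.89.

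Ciliated cell genes rose in 9 of 14 cases with 2 lower at day 14, also adjusted over the list alone (median 0.45, adjusted p = 0.0169; adjusted p = 0.122 with an estimated correlation), including Foxj1, the regulator of motile cilia (1.79), and the axonemal dynein gene Dnah11 (1.92). BMP targets had 8 of 12 higher and 1 lower, also adjusted over the list alone (median 0.41, adjusted p = 0.0195; adjusted p = 0.212 with an estimated correlation), with Id3 (2.13) and Id1 (1.95). Cholesterol biosynthesis genes fell in 14 of 17 cases with 0 higher, also adjusted over the list alone (median -0.43, adjusted p = 2.22e-05; adjusted p = 0.122 with an estimated correlation), such as Fdps (-1.02) and Idi1 (-0.83). The medians of these lists were 0.41, 0.39 and -0.39 with slide as a block and 0.50, 0.31 and -0.50 within slide 2. FGF-ERK feedback genes had 1 higher and 5 lower of 14 at day 14, also adjusted over the list alone (median -0.23, adjusted p = 0.0783, past the threshold in 3 of 21 alternatives, one of them without DA day 14 replicate 1 at 0.0483), and hedgehog genes 7 higher and 3 lower of 17 (median 0.26, adjusted p = 0.391).

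Of 15859 genes tested at day 14, 4144 were higher and 3111 lower in DA cells, 7255 in all, and 443 and 262 of them changed at least 2-fold. The samples of 6584 of the 7255 genes did not overlap between the groups. The count was 7323 with slide as a block, 6016 within slide 2, and 4294 with the close replicates averaged.

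**Figure D3:**
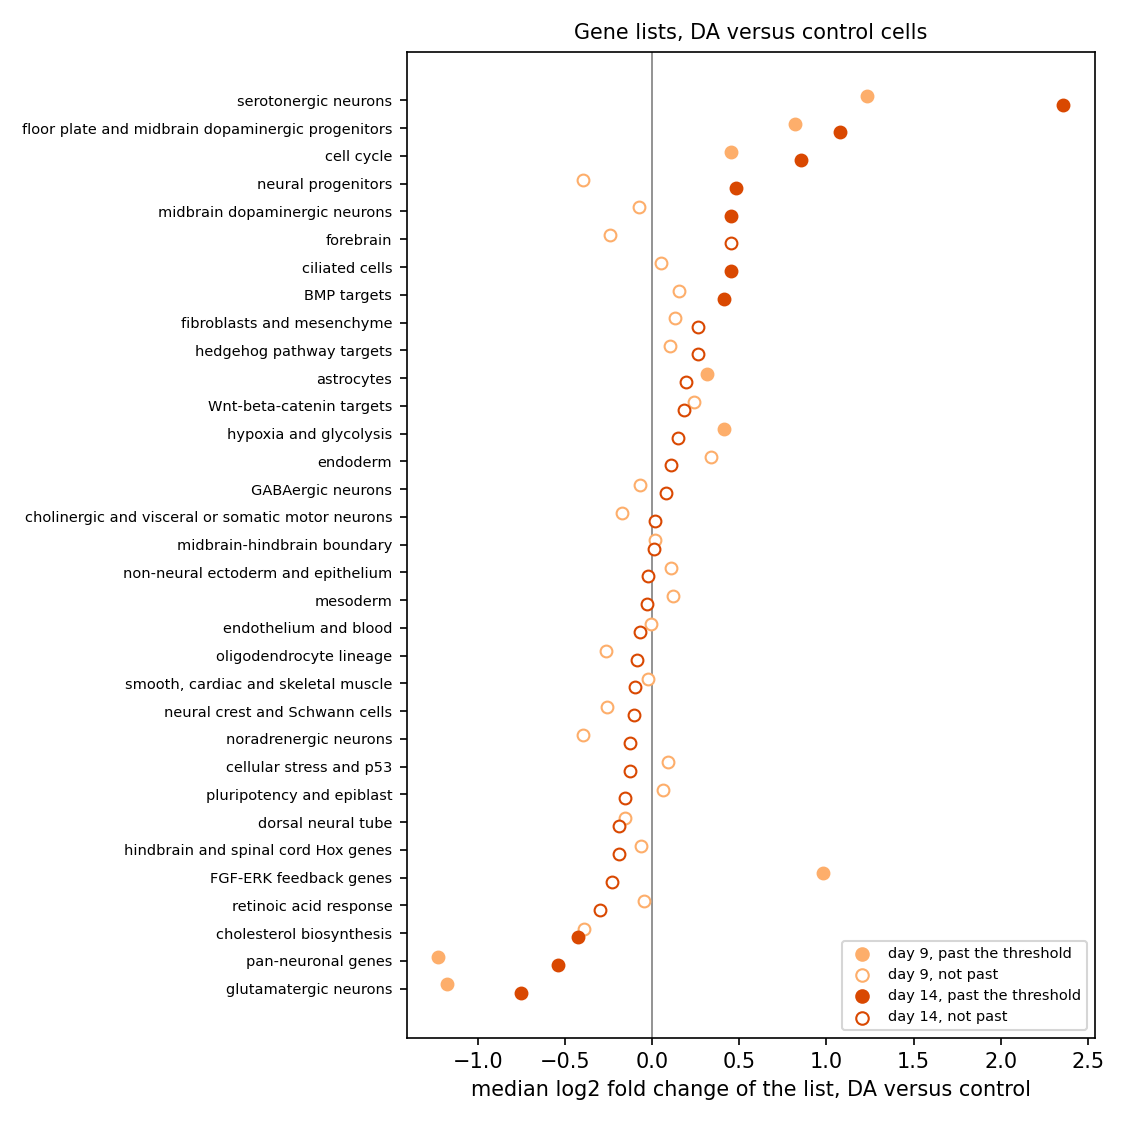
Median log2 fold change, DA over control, of the 33 gene lists at day 9 and at day 14, with filled symbols for lists past the threshold of the list test. The pan-neuronal median was -1.23 at day 9 and -0.54 at day 14, and the serotonergic median was 1.23 and 2.36.

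The arms were also compared with their own earlier day, to ask how each changed with time. From day 5 to day 9 DA cells raised FGF-ERK feedback genes and genes of hypoxia and glycolysis. Among the largest rises were those of Diras2, a small GTPase gene (log2 fold change 4.80, SE 0.0955, adjusted p = 1.69e-12, n = 3), the secretory granule gene Chgb (4.73), Gata3 (4.45) and Ndrg1 (3.42). Pdzph1 (-4.30), the mucin gene Muc4 (-3.52), Dbx1 (-3.46), Ebf2 (-3.14) and Lhx2 (-3.13) fell most. Th (0.90), Foxa2 (1.81), Shh (1.90) and Lmx1a (1.63) rose, and Gli1 fell (-1.53).

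In DA cells over those days FGF-ERK genes had 12 higher and 1 lower of 14 (median 1.76, adjusted p = 2.88e-07, and 0.00839 with an estimated correlation), including Spry1 (3.09) and Dusp6 (3.07). Hypoxia and glycolysis genes had 15 of 16 higher (median 0.95, adjusted p = 1.94e-07), astrocyte genes 6 of 11 (0.23, adjusted p = 0.00476), GABAergic genes 12 of 17 with 2 lower (0.83, adjusted p = 0.000259) and serotonergic genes 6 of 7 (1.41, adjusted p = 0.00505). The GABAergic and serotonergic calls were lost with an estimated correlation (adjusted p = 0.151 and 0.37). Floor plate genes had 13 of 19 higher and 2 lower (0.41, adjusted p = 0.00871, and 0.254 with an estimated correlation). Hedgehog genes had 11 of 17 lower and 2 higher (-0.45, adjusted p = 0.0234), dorsal neural tube genes 10 of 13 lower and 1 higher (-0.49, adjusted p = 0.0203), and cholesterol biosynthesis genes 12 of 17 lower (-0.72, adjusted p = 0.00173). The dorsal and cholesterol calls were lost with an estimated correlation (adjusted p = 0.652 and 0.356). The hedgehog call was lost within slide 2 (-0.56, adjusted p = 0.0521). Adjusted over the list alone, the counts of these 9 lists were the same. With slide as a block the FGF-ERK, hypoxia, astrocyte, GABAergic and serotonergic medians were 1.80, 0.93, 0.23, 0.81 and 1.44, and within slide 2 they were 1.77, 0.91, 0.24, 0.99 and 1.61. The floor plate, hedgehog, dorsal and cholesterol medians were 0.44, -0.44, -0.51 and -0.72 with slide as a block, and 0.38, -0.56, -0.64 and -0.61 within slide 2. In all, 4103 genes rose and 4817 fell, 8920 together, against 9218 with slide as a block, 9598 within slide 2 and 3802 with the close replicates averaged.

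Control cells raised neuronal genes and lowered cell cycle genes from day 5 to day 9, the latter call being lost with an estimated correlation (adjusted p = 0.185). Chl1, a neural adhesion gene, rose most (3.88, SE 0.146, adjusted p = 8.1e-10, n = 3), followed by Lrrn3 (3.78), Lhx9 (3.63), Bcl11a (3.45) and Tfap2b (3.44). Prtg (-3.76), Lin28a, a gene of early embryonic cells (-3.32), Lrtm1 (-3.24), the pluripotency factor gene Sall4 (-3.01) and Clic6 (-2.86) fell most. Th rose from 8.02 ± 0.19 to 10.18 ± 0.14 in control cells (1.98, adjusted p = 1.28e-07), and Foxa2 (-0.80), Shh (-0.43), Wnt1 (-1.25) and Gli1 (-2.06) fell.

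Pan-neuronal genes rose in 26 of 28 cases in control cells (26 higher and 1 lower adjusted over the list alone; median 1.13, adjusted p = 1.47e-13, and 0.0186 with an estimated correlation), including Celf4 (2.32) and Mapt (2.20). GABAergic genes had 12 of 17 higher and 1 lower (14 and 1 adjusted over the list alone; 1.00, adjusted p = 3.19e-07), glutamatergic genes 7 of 10 higher (0.85, adjusted p = 0.00137) and hypoxia and glycolysis genes 12 of 16 higher with 1 lower (0.54, adjusted p = 1.55e-05). Of 22 midbrain dopaminergic neuron genes 8 rose and 0 fell (0.09, adjusted p = 0.0156), and of 14 FGF-ERK genes 7 rose and 1 fell (0.34, adjusted p = 0.0156). Both calls were lost with an estimated correlation (adjusted p = 0.13 and 0.28). Cell cycle genes fell in 24 of 25 cases (25 adjusted over the list alone; -0.61, adjusted p = 1.21e-07, and 0.185 with an estimated correlation) and hedgehog genes in 10 of 17 with 2 higher (13 and 3 adjusted over the list alone; -0.61, adjusted p = 0.0171). The pan-neuronal, GABAergic, glutamatergic and hypoxia medians were 1.13, 1.05, 0.87 and 0.52 with slide as a block, and 1.15, 1.11, 1.03 and 0.48 within slide 2. The dopaminergic, FGF-ERK, cell cycle and hedgehog medians were 0.10, 0.34, -0.57 and -0.60 with slide as a block, and 0.18, 0.30, -0.61 and -0.46 within slide 2. In all, 3108 genes rose and 4023 fell, 7131 together, against 8024 with slide as a block, 7830 within slide 2 and 3575 with the close replicates averaged. Of 871 genes past the threshold within slide 2 with a change of at least 2-fold, 816 moved the same way on slide 1 alone, with 1 sample in each group and no test.

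From day 9 to day 14 DA cells raised neuronal genes and lowered cell cycle and FGF-ERK feedback genes, the calls of these last lists being lost with an estimated correlation (adjusted p = 0.0628 for both). Mlc1, an astrocyte membrane protein gene, rose most (4.21, SE 0.126, adjusted p = 2.35e-11, n = 3), followed by the cannabinoid receptor gene Cnr1 (4.12), Chl1 (4.09), the neuronal splicing regulator gene Rbfox1 (3.997) and the dynein gene Dnah2 (3.84). Rgma (-3.14), the DNA topoisomerase gene Top2a (-3.13), Fndc3c1 (-3.12), Dusp6 (-3.02) and Spry1 (-2.90) fell most. Ddc (2.85), Slc18a2 (2.65), Nr4a2 (1.74), Pitx3 (1.11) and Th (0.79, adjusted p = 0.000102) rose, and Th did not pass with the close replicates averaged, which leaves fewer samples (0.88, adjusted p = 0.0536, from 2.49e-05 over its alternatives). Gli1 (-2.46), Ptch1 (-1.66) and Wnt1 (-1.16) fell.

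Pan-neuronal genes rose in 27 of 28 cases in DA cells over those days (median 2.06, adjusted p = 3.46e-12, and 0.0468 with an estimated correlation), including Mapt (3.49) and the synaptic vesicle gene Syt1 (3.17). Midbrain dopaminergic neuron genes had 14 of 22 higher and 2 lower (0.56, adjusted p = 0.0056), glutamatergic genes 8 of 10 higher (0.90, adjusted p = 0.00823), GABAergic genes 10 of 17 higher and 1 lower (0.57, adjusted p = 0.021), floor plate genes 13 of 19 higher and 3 lower (0.55, adjusted p = 0.0294) and oligodendrocyte lineage genes 9 of 13 higher and 1 lower (0.97, adjusted p = 0.00346), with Gpr17 at 3.66. The dopaminergic, GABAergic, floor plate and oligodendrocyte calls were lost with an estimated correlation (adjusted p = 0.0628, 0.354, 0.307 and 0.154). Cell cycle genes fell in 24 of 25 cases (-2.20, adjusted p = 3.46e-12), FGF-ERK genes in 11 of 14 with 1 higher (-1.27, adjusted p = 0.00016) and hedgehog genes in 13 of 17 with 1 higher (-0.63, adjusted p = 0.0115). The cell cycle and FGF-ERK calls were lost with an estimated correlation. Without DA day 9 replicate 3 the floor plate (0.51, adjusted p = 0.0503) and GABAergic lists (0.52, adjusted p = 0.0563) did not pass. Adjusted over the list alone, the counts of these 9 lists were the same. With slide as a block the pan-neuronal, dopaminergic, glutamatergic, GABAergic and floor plate medians were 2.05, 0.56, 0.90, 0.58 and 0.53, and within slide 2 they were 1.98, 0.59, 0.86, 0.56 and 0.52. The oligodendrocyte, cell cycle, FGF-ERK and hedgehog medians were 1.00, -2.19, -1.28 and -0.63 with slide as a block, and 0.97, -2.14, -1.30 and -0.57 within slide 2. In all, 5157 genes rose and 4856 fell, 10013 together, against 10374 with slide as a block, 10535 within slide 2 and 5434 with the close replicates averaged.

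Control cells from day 9 to day 14 lowered cell cycle and neural progenitor genes, both calls being lost with an estimated correlation (adjusted p = 0.0618 for both). Bcan, a brain extracellular matrix gene, rose most (4.46, SE 0.324, adjusted p = 4.96e-08, n = 3), followed by Egfr (4.08), Plppr4 (3.66), the glutamate receptor gene Grm5 (3.52) and Pcp4 (3.48). Foxn4, a transcription factor gene of neural progenitors, fell most (-4.18), followed by the linker histone gene H1f5 (-3.49), Mki67 (-3.27), Nusap1 (-3.22) and Fndc3c1 (-3.21). Th fell from 10.18 ± 0.14 to 8.38 ± 0.40 (-1.75, adjusted p = 5.86e-08), and Lmx1a (-0.49), Foxa2 (-0.57), Gli1 (-2.19) and Ptch1 (-1.16) fell while Nr4a2 rose (0.69). Foxa2 did not pass without control day 9 replicate 2 (-0.37, adjusted p = 0.108), within slide 2 (-0.79, adjusted p = 0.0507) or with the separate-channel fit (-0.45, adjusted p = 0.0675). Lmx1a (-0.47, adjusted p = 0.0975) and Ptch1 (-0.96, adjusted p = 0.0923) did not pass with the close replicates averaged.

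All 25 cell cycle genes fell in control cells over those days (median -2.58, adjusted p = 4.31e-14) and 14 of 19 progenitor genes fell with 1 higher (14 and 2 adjusted over the list alone; -0.78, adjusted p = 0.002), such as Nes (-1.89). Pan-neuronal genes had 24 of 28 higher and 3 lower (1.33, adjusted p = 8.79e-08), oligodendrocyte lineage genes 10 of 13 higher (1.01, adjusted p = 0.000194), including Pdgfra (3.26), and cholesterol biosynthesis genes 12 of 17 higher and 2 lower (0.37, adjusted p = 0.0354). Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.0618, 0.0618, 0.133, 0.0618 and 0.593 with an estimated correlation, in that order). In that order the medians were -2.57, -0.84, 1.29, 0.99 and 0.39 with slide as a block, and -2.69, -0.94, 1.52, 0.94 and 0.50 within slide 2. In all, 5071 genes rose and 5419 fell, 10490 together, against 10741 with slide as a block, 8553 within slide 2 and 7205 with the close replicates averaged. Of 2124 genes past the threshold within slide 2 with a change of at least 2-fold, 2119 moved the same way on slide 1 alone, with 2 and 1 samples of different dyes and no test.

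The difference between the arms changed from day 9 to day 14, as tested by the interaction of arm and day. FGF-ERK feedback genes lost their excess in DA cells, with 11 of 14 lower and 1 higher on this measure (12 and 1 adjusted over the list alone; median -1.62, adjusted p = 9.8e-08, and 0.013 with an estimated correlation), Spry1 at -3.02 and Etv4 at -2.19. Midbrain dopaminergic neuron genes moved toward DA cells in 13 of 22 cases with 2 the other way, also adjusted over the list alone (0.59, adjusted p = 0.000859, and 0.0359 with an estimated correlation), and so did neural progenitor genes in 14 of 19 with 1 the other way (0.92, adjusted p = 0.000579, and 0.0263 with an estimated correlation), Sox21 (2.46) and Nes (2.01) among them. Floor plate genes had 13 of 19 higher and 2 lower (14 and 2 adjusted over the list alone; 0.78, adjusted p = 0.00093), pan-neuronal genes 17 of 28 higher (19 adjusted over the list alone; 0.74, adjusted p = 3.5e-05) and cell cycle genes 13 of 25 higher (0.47, adjusted p = 0.0154). These last calls were lost with an estimated correlation (adjusted p = 0.122, 0.276 and 0.521 with an estimated correlation). The pan-neuronal call was also lost within slide 2 (0.24, adjusted p = 0.0624) and the cell cycle call without control day 14 replicate 3 (0.36, adjusted p = 0.0687), with 75th percentile scaling (0.27, adjusted p = 0.0525) and with the separate-channel fit (0.23, adjusted p = 0.297).

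With slide as a block the FGF-ERK, dopaminergic, progenitor, floor plate, pan-neuronal and cell cycle medians of this interaction were -1.60, 0.59, 0.98, 0.82, 0.67 and 0.47, and within slide 2 they were -1.30, 0.40, 1.05, 1.04, 0.24 and 0.73. Over all genes, 3750 moved toward DA cells and 2762 toward control cells, 6512 together. The count was 7241 with slide as a block, 4966 within slide 2 and 1919 with the close replicates averaged.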

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

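The tests of fewer neurons of every kind, of more dopaminergic neurons in control cells, of genes shared with other lists, of a larger rise than the dopaminergic genes, and of a slide difference over all samples for Th and for serotonergic genes were chosen after the results were seen.

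The difference between DA and control cells changed between days for 6512 genes, as tested by the interaction of arm and day (limma, n = 3 per group). The lists whose difference moved were FGF-ERK feedback genes (median -1.62), floor plate and midbrain progenitors (0.78), midbrain dopaminergic neurons (0.59), neural progenitors (0.92), pan-neuronal genes (0.74) and cell cycle (0.465). The floor plate, pan-neuronal and cell cycle calls were lost with an estimated correlation (adjusted p = 0.122, 0.276 and 0.521), and the pan-neuronal call also within slide 2 (0.24, adjusted p = 0.0624). Hypoxia and glycolysis genes (-0.245, adjusted p = 0.0569) did not pass here but did in 15 of 27 alternatives (adjusted p from 0.00198 to 0.215), and muscle genes (-0.52, adjusted p = 0.0669) in 9 (0.0188 to 0.521). Robo3, a guidance receptor gene (5.25), Klhl35 (5.03), Pdzph1 (4.15), Dbx1 (3.82) and Ddc (3.56) moved most toward DA cells. Egfr (-5.19), Camkv (-3.36), Mtss1 (-3.16), Etv5 (-3.07) and Mfge8 (-3.04) moved most toward control cells. Among the genes named in advance, Th (2.54), Slc18a2 (2.49), Pitx3 (1.08), Nr4a2 (1.05) and Lmx1a (1.25) moved toward DA cells and Wnt1 (-1.02) toward control cells.

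Probes without a gene name, which no comparison above used, also changed between DA and control cells: 3210 of 15714 at day 9 and 3187 at day 14, of which 281 and 158 changed at least 2-fold.

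Other splits of the samples were fitted with a correlation from 1500 genes, so their counts differ slightly from those above. With 3 samples against 3 there are 10 splits, too few for a share under 0.05, and in each comparison of 2 groups 1 of the 10, the real one, gave as many genes. The real splits gave 8035 genes for DA against control cells at day 9, 7323 at day 14, 8991 for DA day 9 against day 5, 7173 for control day 9 against day 5, 10076 for DA and 10542 for control cells between days 9 and 14. The highest other split gave 1 gene in DA cells between days 9 and 14 and 0 in the others. For the interaction 2 of 100 splits gave at least as many genes as the real one (6590), the real one included, and the other one gave 6818. Splits that mix days widen the spread whether or not an interaction exists, so this share does not exclude chance. That split had 5 of the 6 day 9 samples on one side and 5 of the 6 day 14 samples on the other, so it mostly compared days. The interaction gave 7241 genes with slide as a block and 4966 within slide 2.

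Pan-neuronal genes were lower in DA than in control cells at day 9, 25 of 28, although the list call was lost with an estimated correlation (adjusted p = 0.0582). A slide difference is argued against by the median within slide 2 (-1.21, 24 genes lower, 3 DA and 2 control samples), and a dye difference by the median between the Cy3 samples alone (-1.33, 27 genes lower). Fewer neurons of every kind would lower GABAergic genes alike. The mean log2 fold change of the GABAergic list lay 1.16 above that of the pan-neuronal list (two-sided permutation p over genes = 6e-05). That permutation treats genes as independent, and most GABAergic list members are transcription factors, some of which progenitors also make. The comparison therefore does not decide whether DA cells held fewer neurons. Treatment is the difference the design names. From day 5 to day 9 the list median was 0.0238 in DA cells and 1.13 in control cells. The gap between the medians at day 9 thus reflects a rise in control cells that the median in DA cells did not show. This does not hold for each member. Dcx averaged 11.13 at day 5 and, at day 9, 9.91 in DA and 12.3 in control cells. How treatment led to the gap was not tested.

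Th was higher in control cells at day 9 and in DA cells at day 14. A slide difference is argued against by the values over all samples with slide as a block, -1.149 at day 9 and 1.424 at day 14, both past the threshold, while the values within slide 2 (-1.108 and 1.418) rest on 1 control sample at day 14 and decide nothing for that day. Th has only 1 probe, so 0 other probes gave an opposite call and a fault of that probe cannot be told apart from a change of the gene. More dopaminergic neurons in control cells at day 9 would raise other genes of those neurons there, and of Ddc, Slc18a2, Slc6a3, Pitx3 and Nr4a2, 0 were lower in DA cells over all samples and 1 was higher (Ddc, 1.15), but within slide 2 Ddc (0.98, adjusted p = 0.0527) narrowly missed the threshold at a similar fold and Nr4a2 was lower (-0.32, against -0.23 over all samples), so the test leaves this undecided. Treatment is the difference the design names, and which cells made Th was not tested.

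Serotonergic genes were higher in DA cells at day 14, although the list call was lost with an estimated correlation (adjusted p = 0.122). A slide difference is argued against by the list over all samples with slide as a block (median 2.17, all 7 genes higher), while the calls of Tph2, Fev and Slc6a4 within slide 2, 3 of 3, rest on 1 control sample and decide nothing. The rise was not confined to genes shared with other lists, such as Ddc and Gata3. Tph2, Fev and Slc6a4, which no other list holds, had a fitted median of 3.165, or 3.29 with Tph2 and Slc6a4 at their bounds. How far shared genes made the list call is not decided by this, since Tph2 and Slc6a4 were among the largest rises. The mean of Tph2, Fev and Slc6a4 lay 2.18 log2 units above that of Th, Slc6a3, Pitx3, Nr4a2, En1 and Aldh1a1. That difference decides nothing, since Tph2 and Slc6a4 were among the largest rises and have only bounds, and since Ddc (4.71), Gch1 (3.14), Lmx1a (2.88) and Slc18a2 (2.69), not in that set, rose as well. A hypothesis that stays open is that the DA cultures may have held serotonergic neurons beside dopaminergic ones, which RNA of whole cultures cannot separate. Of the serotonergic list, Maob, Htr1a, Htr1b and Slc22a3 were not among the genes tested.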

How the results depend on the processing

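The averaging of close replicates and the values on slide 1 alone were chosen after the data were seen, and the other alternatives before.

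Counts of genes past the threshold stayed within 1.5 times the reported count in 92 alternatives other than leaving out a replicate, and in all 48 that left out 1. The 6 that moved further came with the replicates closer than spot noise averaged, which leaves fewer samples: 3536 for DA against control cells at day 9, 4294 at day 14, 3802 for DA day 9 against day 5, 3575 for control day 9 against day 5, 5434 for DA day 14 against day 9 and 1919 for the interaction, while 7205 remained for control day 14 against day 9. Genes called in both fits had the same sign in at least 99.1% of cases in each of 146 fits. Leaving out a replicate gave 6882 to 7446 genes for DA against control cells at day 9, 5920 to 7079 at day 14, 7399 to 8690 for DA day 9 against day 5, 5816 to 7374 for control day 9 against day 5, 8884 to 9882 for DA and 8928 to 10452 for control cells between days 9 and 14, and 4942 to 7206 for the interaction.

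Among values of named genes past the threshold, 5 changed sign. Sign changes of values not past it were not counted. With processed signals it was Fgf4 in the interaction (-0.59). With the mean over probes it was Csf1r in DA day 14 against day 9 (-0.15). Another probe of Csf1r was called the opposite way there (-0.721, adjusted p = 0.000441, against 0.423), which turned the mean. With 75th percentile scaling they were Klf1 (0.00867) and Pecam1 (0.0331) in DA day 9 against day 5 and Eno1 in DA day 14 against day 9 (-0.0307). For genes other than Csf1r the cause was not tested. With 75th percentile scaling the median of all genes in DA day 14 against day 9 was -0.108, against 0.0225 as reported, and 42% of called genes were higher. Of the other values of named genes, 491 lost and 36 gained the call, and 244 and 15 did so without a replicate. For lists, 62 lost and 59 gained it, and 8 and 22 without a replicate. Of the 62, 35 were lost with an estimated correlation, which gave the highest adjusted p over the alternatives of each list past the threshold in the comparisons of DA with control cells and in the interaction, except astrocytes and glutamatergic genes. With at least 8 channels above background the calls of hedgehog genes in control day 9 against day 5 (adjusted p = 0.0509) and of dorsal genes in DA day 9 against day 5 (0.0841) were lost, as was that of hedgehog genes there with the mean over probes (0.15). With processed signals the calls of floor plate (0.0538) and GABAergic genes (0.107) in DA day 14 against day 9 were lost, and with only the groups compared that of ciliated cell genes at day 14 (0.0539). The causes were not tested.

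With the replicate number as a block the counts were 7466, 6947, 7740, 6569, 8939, 9418 and 5763 in the order above, none of them over 1.5 times away. Whether the numbers pair the samples stays unclear. The median correlation of deviations was 0.0872 for pairs with the same number and -0.0723 for other pairs. By slide it was 0.0724 and -0.126, and by dye 0.0763 and -0.0576. Of 30 pairs with the same number 15 lay over 0.1 (range -0.422 to 0.578), and 7 of 15 samples were closest to their own number. With only the groups compared, the array correlation was set to 0 in the 6 comparisons of 2 groups and was 0.359 in the interaction. Genes near background limit these arrays, since the signal there sits on the offset.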

Other observations

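No test in this part was chosen after the results were seen, other than the choice of the unnamed probes given last.

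Genes of brain regions other than the ventral midbrain moved singly between DA and control cells, and their lists did not pass in the fit over all samples. The forebrain list had 5 genes higher and 6 lower of 13 at day 9 (adjusted p = 0.86) and 7 and 2 at day 14 (0.45, adjusted p = 0.107), where Dmrta2 (1.51) and Barhl1 (1.49) were higher while Lhx2 was lower. Dorsal neural tube genes had 3 higher and 6 lower of 13 at day 9 and 3 and 4 at day 14 (-0.19, adjusted p = 0.266), where Pax3 was lower (-1.77) and Zic1 (1.21) and Wnt3 (1.18) higher. Midbrain-hindbrain boundary genes had 3 higher and 2 lower of 10 at day 14 (median 0.01, mean and test below 0, adjusted p = 0.797), with Fgf18 lower (-1.001). Of 7 Hox genes of the hindbrain and spinal cord 0 rose and 4 fell at day 14 (-0.19, adjusted p = 0.058), and the list passed in 4 of 21 alternatives (adjusted p from 0.0208 to 0.221). GABAergic genes had 8 higher and 4 lower of 17 at day 14 (0.08, adjusted p = 0.239), with the homeobox genes Dlx2 (2.49) and Dlx1 (1.63) and the transcription factor gene Gata2 (1.83) higher. Cholinergic and motor neuron genes had 3 higher and 3 lower of 11 (median 0.02, mean and test below 0, adjusted p = 0.838), and noradrenergic genes 1 and 2 of 5 (-0.13, adjusted p = 0.28).

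Further lists did not pass there at day 14 or at day 9, as given for each. At day 14 pluripotency genes had 0 higher and 7 lower of 20 (-0.16, adjusted p = 0.0554), such as Esrrb (-1.36) and Fgf4 (-1.35). This list passed in 7 of 21 alternatives (adjusted p from 0.00598 to 0.158), among them without DA day 14 replicate 1 (-0.20, adjusted p = 0.0393), without DA day 14 replicate 2 (-0.25, adjusted p = 0.0304) and without control day 14 replicate 3 (-0.20, adjusted p = 0.0467). Retinoic acid response genes had 2 higher and 5 lower of 10 (-0.30, adjusted p = 0.058), with the retinoic acid-degrading enzyme gene Cyp26b1 at -1.80, and passed in 4 of 21 alternatives (adjusted p from 0.028 to 0.122), among them without control day 14 replicate 3 (-0.35, adjusted p = 0.0288). Oligodendrocyte lineage genes had 2 higher and 5 lower of 13 (-0.09, adjusted p = 0.222), with Olig1 (-1.73) and Pdgfra (-1.61) lower, and astrocyte genes 4 and 2 of 11 (0.20, adjusted p = 0.488). Mesoderm genes had 5 higher and 3 lower of 13 (-0.03, adjusted p = 0.796), endoderm genes 2 and 0 of 6 (0.11, adjusted p = 0.239), neural crest genes 2 and 4 of 11 (-0.10, adjusted p = 0.262), and non-neural ectoderm genes 4 and 1 of 15 (median and test below 0, mean 0.06, adjusted p = 0.984). Fibroblast genes had 6 higher and 1 lower of 18 (0.27, adjusted p = 0.143), among them the collagen gene Col5a1 (1.63), and this list passed within slide 2 with 1 control sample (0.50, adjusted p = 0.0043), without control day 14 replicate 1 (0.41, adjusted p = 0.00382) and without DA day 14 replicate 2 (0.30, adjusted p = 0.0419), with adjusted p up to 0.625 over its alternatives. Muscle genes had 1 higher and 2 lower of 9 (-0.10, adjusted p = 0.274), endothelium and blood genes 1 and 2 of 9 (-0.07, adjusted p = 0.274), Wnt targets 5 and 1 of 13 (0.18, adjusted p = 0.266), hypoxia and glycolysis genes 5 and 4 of 16 (0.15, adjusted p = 0.529), and genes of stress and p53 5 and 7 of 17 (-0.13, adjusted p = 0.274). At day 9 cholesterol biosynthesis genes had 1 higher and 9 lower of 17 (-0.39, adjusted p = 0.0783; past the threshold in 4 of 21 alternatives, from 0.0328 to 0.631, one of them without DA day 9 replicate 1 at 0.0355), BMP targets 6 and 3 of 12 (0.15, adjusted p = 0.499), ciliated cell genes 5 and 0 of 14 (0.05, adjusted p = 0.259), and neural progenitor genes 3 and 9 of 19 (-0.40, adjusted p = 0.235), with Hes5 (-2.11) and Sox3 (-2.12) lower.

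In the other comparisons some lists passed only in alternatives, with adjusted p over all samples given here. From day 5 to day 9 these were midbrain dopaminergic neuron genes in DA cells (0.0576, past in 5 of 21) and cholesterol biosynthesis genes in control cells (0.129, past in 6). From day 9 to day 14 they were Wnt targets in DA cells (0.0644, past in 3) and, in control cells, hedgehog genes (0.0572, past in 5) and astrocyte genes (0.0572, past in 6). Serotonergic genes passed for the interaction in 2 of 27 (0.122). Mesoderm and pluripotency genes for the interaction, astrocyte genes and genes of stress and p53 in control cells from day 5 to day 9, and hypoxia and glycolysis genes in control cells from day 9 to day 14 passed in 1 alternative each.

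Some of the probes without a gene name that changed most lie in 3 regions of the array design (mm9). On chromosome 2 between 33500594 and 33501874, forward strand, 3 probes were higher in DA cells by 1.77, 1.98 and 1.52 log2 units at day 9 and by 3.06, 2.96 and 2.69 at day 14. On chromosome 13 between 98635795 and 98646617, reverse strand, the log2 fold change of 1 probe was -2.08 at day 9 and -2.95 at day 14. On chromosome 16 between 46384974 and 46391331, reverse strand, 5 probes were higher by 2.05 to 2.23 log2 units at day 14 and lay between -0.39 and -0.15 at day 9. These regions were picked from those with the largest changes, without a fixed rule, and no transcript is named for them here. Other regions changed more than that on chromosome 16 and are not described. Among them were regions on chromosome 2 from 108456668 (-2.79 at day 14) and on chromosome 5 from 52998788 (-2.77), both lower in DA cells.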
